A study of Homo sapiens with 6 samples.

How the data were processed

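Gene expression was measured in MDA-MB-231 cells by strand-specific poly(A) RNA-seq, in 3 cultures given a negative-control siRNA (siNC) and 3 given an siRNA against BYSL (siBYSL), which the labels call independent biological replicates. Per the labels' protocols, 160 pmol siRNA and 4 µL Lipofectamine RNAiMAX were used per well, the medium was changed at 6 h, RNA was taken at 48 h, and reads were 150 nt paired-end from a NovaSeq X Plus. The sequence of the control siRNA is not in the labels. The deposited file holds raw counts per gene for the 6 libraries, as whole numbers under versioned Ensembl identifiers. HISAT2, DESeq2 and genome build GRCh38.p13 are named without version or role, per the submitters' processing notes. The counting tool, the annotation release and any filter are not given in the sources used here. The table held 29538 genes, each with at least 1 count, with a repeated symbol in 207 entries, which were kept apart by identifier.

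Analyses ran in R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0) and Python 3.11.15 (NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, Matplotlib 3.10.9). Counts were filtered with filterByExpr by group, leaving 16412 genes, and scaled with TMM factors, which ran from 0.9645 to 0.9806 in siNC and from 1.011 to 1.04 in siBYSL. siBYSL was compared with siNC by the edgeR quasi-likelihood F test (robust, group-only design), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Adjusted p for single genes in the report come from this test. The SE of a gene was derived from it, as the absolute log2 fold change divided by the square root of the F statistic. Such p-values describe variation between 3 and 3 cultures of a single line. Library totals of 27754883 to 32088817 counts and a common biological coefficient of variation of 0.0649 set the precision, and genes of low count carry wider errors. CPM values use TMM-scaled library sizes, and principal components used the 500 most variable genes in log2 CPM with a prior count of 2.

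The gene lists, the tests of the report, the naming rule and all alternatives but 3 were fixed before the data were examined; tests of heptamers of a control siRNA and of ZNF genes, given under other observations, were added later. Named genes were BYSL, then the 12 largest rises and 12 largest falls among genes with an adjusted p under the threshold, a mean of 10 CPM or more, a proper symbol and no overlap between groups, and up to 4 members of each list with the smallest p. Some genes that met this rule are not reported here. There were 41 gene lists, with BYSL left out of each, covering ribosome assembly, ribosomal proteins, cell cycle, stress, signalling, metabolism, adhesion, cell death and markers of other cell types. The 40 lists with 5 or more tested members were tested with camera (two-sided, voom log2 CPM, preset inter-gene correlation 0.01, Benjamini-Hochberg over lists). The same test with an estimated correlation, and the self-contained test fry, stood beside it. Member calls were made over all genes and again adjusted over the list alone. Gene classes were those given with the deposited counts. Coordinates, transcript lengths and 3′ UTRs came from GENCODE 29, which may differ from the submitters' annotation.

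For the seed test, the strands of the BYSL siRNA were read from the labels, and the longest annotated 3′ UTR of a protein-coding transcript of each gene was searched for the reverse complement of bases 2 to 8. Fold changes were adjusted for 3′ UTR length by a lowess fit (share 0.5), and the difference between genes with and without a site was tested with 100000 two-sided permutations over genes and ranked among heptamers of the same base composition.

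The tests were tried on simulated data. With 200 genes changed, edgeR called 42.9% of genes changed by a factor of 1.25, 82.0% at 1.5, 87.8% at 2 and 100% at 4, all in the right direction, with 9 false calls among 16211 genes. Camera called a list shifted by 0.25 on the log2 scale and 0 unshifted lists that shared no member with it. Simulated genes were drawn independently, so this cannot show how often lists of correlated genes are called falsely. In the real data the estimated correlation was 0.97 for both ribosomal protein lists. The seed test gave a difference of 0.0016 with no effect built in and -0.10 for a true -0.15; the cause of the shortfall was not tested. Sets matched on length, GC content and expression gave 936 of 1000 sets as high under a length trend alone and 0 under a shift of 0.20.

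Alternatives were DESeq2 size factors, library totals, upper-quartile factors, no filter, a stricter filter (1 CPM or more in at least 3 libraries), the DESeq2 Wald test, limma-voom, a block on replicate number, each library left out in turn and mitochondrial transcripts left out. For the seed test they were all annotated 3′ UTRs, genes of 10 CPM or more and the block. Added after the data were seen were removal of each library's trend with transcript length, for genes and for lists, and list tests without guide-site genes. Splicing and sequence variants were not analysed, since counts per gene carry neither.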

Results

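The study asked how the transcriptome of MDA-MB-231 cells responded when BYSL was depleted. MDA-MB-231 is an established line of invasive human breast cancer cells with a mesenchymal character. BYSL encodes bystin, a factor needed for maturation of the small (40S) ribosomal subunit. Cells received 160 pmol per well of either a negative-control siRNA (siNC, 3 cultures) or an siRNA against BYSL (siBYSL, 3 cultures), and RNA was taken 48 h later. The 3 libraries of each group came from separate biological replicates. Strand-specific poly(A) RNA-seq gave 28606048 to 30476744 counted reads per siNC library and 27754883 to 32088817 per siBYSL library. Counts were found for 23331 to 23629 genes per siNC library and 23849 to 24394 per siBYSL library, and the 10 most abundant genes held 10.1% to 10.6% of the counts. Transcripts of the mitochondrial genome held 10.86% ± 0.21 of counts in siNC and 10.83% ± 0.27 in siBYSL (SD, n = 3 each). Annotated rRNA genes, which include the mitochondrial MT-RNR1 and MT-RNR2 already counted in that share, held 0.96% ± 0.012 in siNC and 1.11% ± 0.069 in siBYSL. This was mostly mitochondrial rRNA: MT-RNR2 stood at 8457 CPM in siNC and 9398 CPM in siBYSL, and MT-RNR1 at 1414 and 1442 CPM. Neither gene was called (edgeR adjusted p = 0.0541 and 0.899). lncRNA genes held 1.24% ± 0.021 and 1.36% ± 0.060. In both classes every siBYSL library lay above every siNC library. The first principal component of the 500 most variable genes held 68.8% of their variance and separated the groups. Pairs of libraries within a group correlated at r = 0.9918 or above over log2 CPM, and pairs across groups at 0.9872 or below, over genes, which are not independent replicates. Library siBYSL 3 stood apart from the other siBYSL libraries: its chi-square per degree of freedom was 22.0 against siBYSL 1 and 13.5 against siBYSL 2, while siBYSL 1 and 2 differed by 3.42.

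BYSL itself fell to 16.4% of its control level. Its mean was 99.9 ± 4.9 CPM (counts scaled to library size) in siNC and 16.4 ± 0.94 CPM in siBYSL (SD, n = 3 each). The raw counts were 2908, 2648 and 3006 in siNC 1 to 3 and 459, 519 and 502 in siBYSL 1 to 3. The log2 fold change was -2.61 (SE 0.067, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.4e-09), and every library thus followed its label. BYSL (ENSG00000112578.10) lies on chromosome 6 from 41921188 to 41933046 on the plus strand of GRCh38. The 19 bases matched by the siRNA, GAGATGACGTTGCTGAATA, lie at 41931467 to 41931485, in coding sequence within exon 5 of the 7 exons of transcript BYSL-201. No annotated transcript of another gene held a perfect match to these bases.

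**Figure D1:**
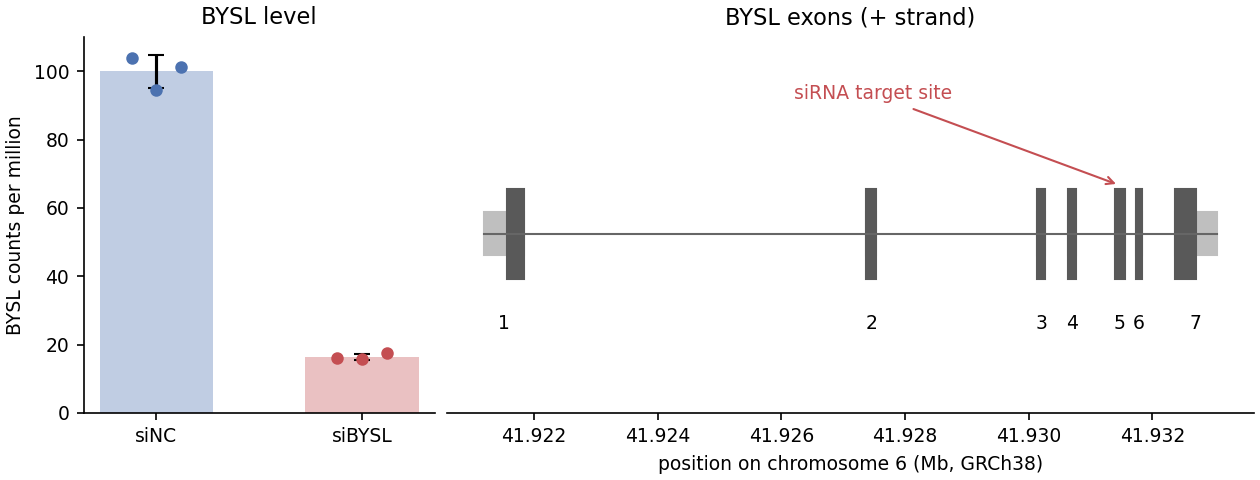
Left, BYSL CPM in each library (points), with bars at the group mean and error bars of 1 SD (n = 3 per group). The siBYSL libraries lie near 16.4 CPM and the siNC libraries near 99.9 CPM. Right, exons of BYSL-201 along chromosome 6 (Mb, GRCh38), with coding sequence as tall dark boxes, untranslated sequence as low grey boxes and the siRNA target site marked in exon 5.

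Expression changed widely beyond BYSL. Of 16412 genes tested, 3032 were higher and 3027 were lower in siBYSL at an adjusted p under 0.05, 6059 in all. Most changes were small: 360 genes rose and 153 fell by 1 or more on the log2 scale. The balance of directions depended on scaling. With library totals alone 4106 genes were higher and 1989 lower (67.37% higher, against 50.04% with TMM factors), and with upper-quartile factors 3630 were higher and 2418 lower (60.02%). The count of genes higher by 1 or more fell to 209 under a stricter filter on low counts, which tested 14183 genes.

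The 12 largest named rises ran from 1.71 to 1.22 on the log2 scale. IGFBPL1 (ENSG00000137142.5), an insulin-like growth factor binding protein-like gene on chromosome 9, rose from 10.9 ± 0.72 to 35.6 ± 1.6 CPM (log2 fold change 1.71, SE 0.074, adjusted p = 2.6e-07). FBN1, which encodes the microfibril protein fibrillin-1, rose by 1.56 to 54.0 ± 5.3 CPM, and COL7A1, the anchoring-fibril collagen, rose by 1.31. SOX4, a transcription factor of the SOX family, rose from 27.6 ± 1.2 to 70.1 ± 1.2 CPM (1.35, SE 0.058). The natriuretic peptide clearance receptor NPR3 rose by 1.31 and podocalyxin, PODXL, by 1.26 to 315.2 ± 28.1 CPM. Others were the histone gene H2BC5 (1.30), RGS19 (1.30), the zinc-finger gene ZNF845 (1.28), PALM (1.28) and BCL7A (1.22). H2BC5 and ZNF845 belong to families of similar sequence in which reads can be shared.

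The 12 largest named falls ran from -1.88 to -1.36. IDH1 (ENSG00000138413.14), the cytosolic isocitrate dehydrogenase, fell from 158.3 ± 4.6 to 43.1 ± 2.7 CPM (log2 fold change -1.88, SE 0.059, adjusted p = 3.0e-08). CDKN1A (ENSG00000124762.14), which encodes the cell-cycle inhibitor p21, fell from 129.2 ± 1.1 to 37.7 ± 0.78 CPM (-1.78, SE 0.050). The cytokine genes IL11 and IL24 fell as well (-1.86 and -1.77). EIF2S1, the alpha subunit of translation initiation factor eIF2, fell from 262.2 ± 1.2 to 93.4 ± 4.0 CPM (-1.49), and the microtubule-destabilizing STMN1 fell from 771.9 ± 27.9 to 300.5 ± 12.2 CPM (-1.36). ERRFI1, a feedback inhibitor of the EGF receptor, fell by 1.48. The others were RAB3IP (-1.53), the outer mitochondrial membrane protein gene TSPO (-1.52), HMGN4 (-1.48), ENTPD3 (-1.47) and PIGS (-1.36).

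**Figure D2:**
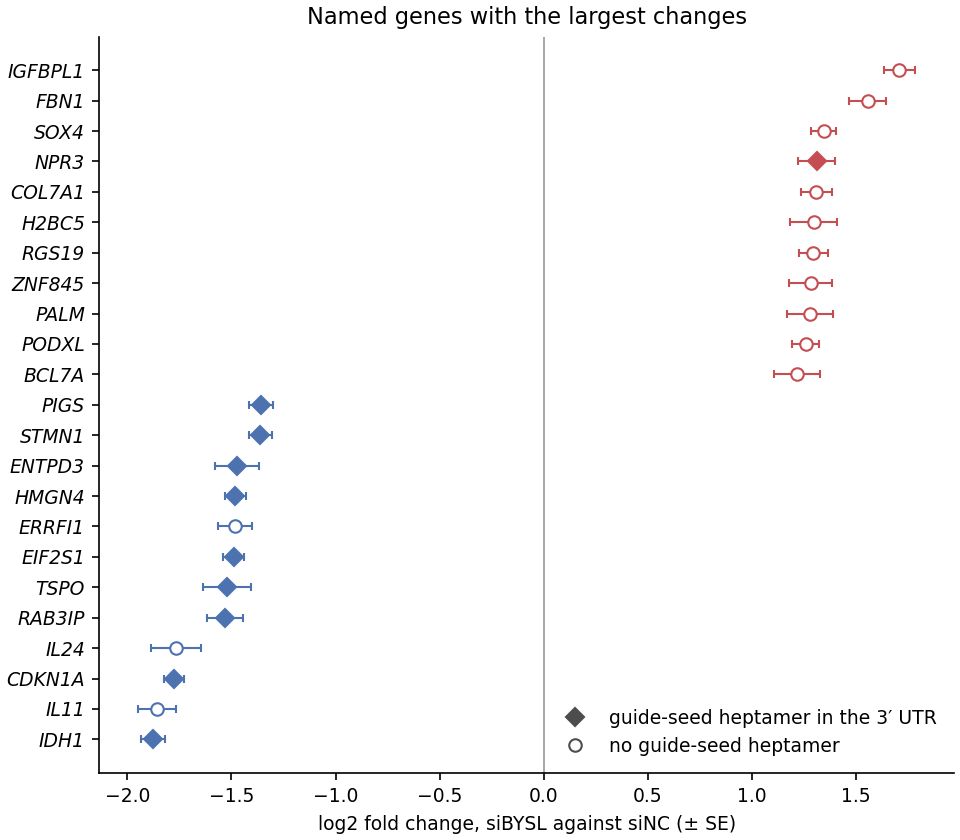
Log2 fold change of siBYSL against siNC with its SE for 11 of the 12 largest rises (red) and the 12 largest falls (blue) under the naming rule, from 3 libraries per group. Filled diamonds mark genes with a guide-seed heptamer in the annotated 3′ UTR, which 9 of the falls and 1 of the rises shown carried.

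siRNA strands can lower transcripts whose 3′ UTR pairs with the seed, bases 2 to 8 of the strand, so the fold changes were compared between genes with and without such sites. Of 13062 tested genes with an annotated 3′ UTR, 1548 (11.9%) held the heptamer GCTGAAT, which pairs with the seed of the guide (antisense) strand of the BYSL siRNA. Those genes lay lower than the others by -0.16 on the log2 scale (SE 0.012) after adjustment for 3′ UTR length. A two-sided permutation test over genes gave p = 1e-05, the smallest that 100000 permutations can give. This was the lowest difference among 630 heptamers of the same base composition, the next being -0.089. The 412 genes with the octamer GCTGAATA differed by -0.24 (SE 0.025). Of genes with no site 19.2% fell, against 32.5% of genes with 1 site and 41.6% of genes with 2. Sites of the passenger strand (GTCATCT) gave a smaller difference of -0.052 (SE 0.011), rank 5 of 420. Of the genes that fell and had a 3′ UTR, 523 of 2732 (19.1%) held a guide-seed heptamer, as did 233 of 2599 that rose (8.97%) and 792 of 7731 not called (10.2%). Among genes that fell by 1 or more on the log2 scale the share was 48 of 114 (42.1%). Of the named falls, IDH1, CDKN1A, RAB3IP, TSPO, EIF2S1, HMGN4, ENTPD3, STMN1 and PIGS carried the heptamer, and IL11, IL24 and ERRFI1 did not. NPR3 carried it among the named rises.

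**Figure D3:**
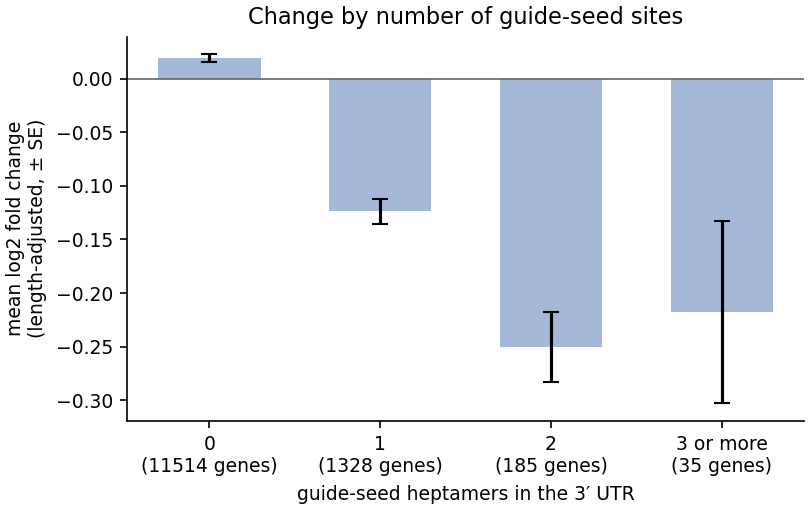
Mean log2 fold change, siBYSL against siNC, after removal of the trend with 3′ UTR length, for genes grouped by the number of guide-seed heptamers in the 3′ UTR; error bars are the SE over genes and gene numbers stand under the bars. The mean is 0.019 without a site, -0.12 with 1 site, -0.25 with 2 sites and -0.22 with 3 or more. The last bar rests on 35 genes (SE 0.085).

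Genes for assembly of the ribosome were lower as groups. Of 67 tested factors of 40S assembly, the process in which bystin acts, 34 fell and 2 rose (37 and 3 adjusted over the list alone), with a median log2 fold change of -0.19 (-0.11 with library totals). The small-subunit processome component NOL6 fell by 0.79, PNO1, which joins the pre-40S particle, by 0.60, UTP4 by 0.41 and the export factor RRP12 by 0.43. NOL6 carried a guide-seed heptamer, but only 2 of the 34 fallen factors did. Of 61 factors of the large (60S) subunit, 27 fell and 4 rose (the same counts adjusted over the list alone), with MRTO4 at -0.58, the rRNA methyltransferase NOP2 at -0.48 and RRS1 at -0.48, while GLE1, also a factor of mRNA export, rose by 0.73. NOP2 carried a guide-seed heptamer. Of 19 host genes of small nucleolar RNAs 10 fell and 0 rose (10 adjusted over the list alone), among them SNHG1 (-0.53), SNHG15 (-0.58), SNHG3 (-0.40) and SNHG32 (-0.28). The camera test, which compares a list with all other genes, gave adjusted p = 1.2e-05 for 40S factors, 6.3e-05 for 60S factors and 5.2e-04 for the host genes. With an estimated correlation between genes these became adjusted p = 0.134, 0.0978 and 0.492. Of 18 genes of the RNA polymerase I machinery 6 fell and 3 rose (the same adjusted over the list alone; camera adjusted p = 0.253). NOLC1 rose by 0.88 and TCOF1, which promotes rRNA gene transcription, by 0.53, while the polymerase subunits POLR1C and POLR1G fell by 0.48 and 0.39.

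Ribosomal protein genes lay slightly lower, but not in every siBYSL library. Of 47 genes for large-subunit proteins 9 fell and 0 rose (2 fell adjusted over the list alone; median -0.16, or -0.080 with library totals), led by RPL10 (-0.36) and RPL41 (-0.38). None of the 32 genes for small-subunit proteins passed the test (0 adjusted over the list alone as well); RPS3 stood at -0.25 with adjusted p = 0.0567. Camera gave adjusted p = 0.00421 and 0.0317, and adjusted p = 0.742 for both with an estimated correlation. The median of the 79 genes against the siNC mean was -0.34 in siBYSL 1 and -0.20 in siBYSL 2 but 0.11 in siBYSL 3. In the same libraries 411 other protein-coding genes with transcripts under 1000 bases had medians of -0.20, -0.11 and 0.091. Without siBYSL 1 the adjusted p was 0.217 for large-subunit and 0.474 for small-subunit genes. The small-subunit call was also lost without siNC 1 (adjusted p = 0.13), without siBYSL 2 (0.0909) and under the stricter filter (0.0611). Of 57 genes for mitochondrial ribosomal proteins 16 fell and 1 rose (15 and 1 adjusted over the list alone; MRPS2 -0.44, MRPL19 -0.31, MRPL33 -0.40). Their camera adjusted p was 0.00415, or adjusted p = 0.702 with an estimated correlation and 0.0815 without siBYSL 1.

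Cell-cycle and MYC lists held more falls than rises. Of 50 genes of the G1/S transition and DNA replication 25 fell and 1 rose (27 and 1 adjusted over the list alone; camera adjusted p = 7.4e-07; adjusted p = 0.134 with an estimated correlation). The cohesion factor DSCC1 fell by 0.74, the clamp loader subunit RFC5 by 0.57, thymidylate synthase, TYMS, by 0.44 and cyclin E1, CCNE1, by 0.60. DSCC1 and RFC5 carried a guide-seed heptamer, as did 5 of the 25 fallen members in all. Of 54 genes of G2/M and mitosis 17 fell and 4 rose (the same adjusted over the list alone), with PLK1 at -0.51, CDC20 at -0.55 and MAD2L1 at -0.46. Camera gave adjusted p = 0.0321 for this list, but adjusted p = 0.661 with an estimated correlation, 0.258 without siBYSL 3, 0.111 with library totals and 0.0617 under the stricter filter. Of 36 MYC target genes 25 fell and 2 rose (28 and 2 adjusted over the list alone; median -0.28; camera adjusted p = 7.4e-07, and adjusted p = 0.0978 with an estimated correlation). SHMT2, the mitochondrial serine hydroxymethyltransferase, fell by 0.57, the amino acid transporter SLC7A5 by 0.56 and lactate dehydrogenase A, LDHA, by 0.45, against the rise of NOLC1. Replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, went both ways: of 17 tested 5 rose and 2 fell (the same adjusted over the list alone). Their camera adjusted p was 0.13, or 0.00898 under the stricter filter and 0.661 with an estimated correlation. H2AC6 rose by 0.86 and H4C8 by 0.98.

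**Figure D4:**
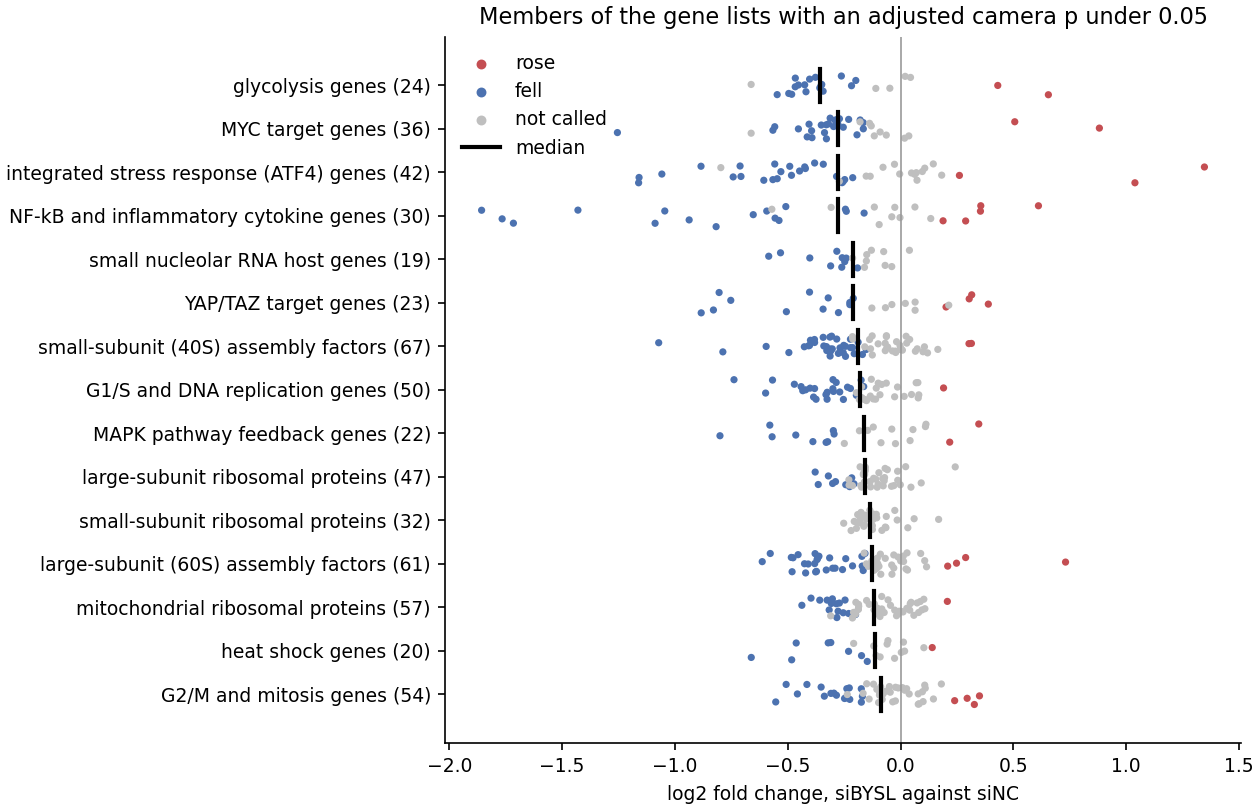
Log2 fold change, siBYSL against siNC, of each tested member (points) of the 15 gene lists with a camera adjusted p under 0.05; list sizes stand in brackets, colours show members that rose, fell or were not called, and black lines mark medians. None of the 15 keeps an adjusted p under 0.05 with an estimated correlation; all medians lie below 0, from -0.085 for G2/M genes (-0.0069 with library totals) to -0.36 for glycolysis genes.

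Glycolysis had the lowest median among those 15 lists. Of 24 genes 17 fell and 2 rose (the same adjusted over the list alone; median -0.36; camera adjusted p = 1.2e-05, and adjusted p = 0.0978 with an estimated correlation). ENO2 fell by 0.55, PGAM1 by 0.48 and the glucose transporter SLC2A1 by 0.47, while the liver-type phosphofructokinase PFKL rose by 0.66. LDHA, at 2716 CPM in siNC and 1984 CPM in siBYSL, belongs to this list as well. Hypoxia targets overlap it: of 27, 10 fell and 5 rose (the same adjusted over the list alone; camera adjusted p = 0.0755), with BNIP3 at -0.53, EGLN3 at -1.07 and CA12, which rose and carried a guide-seed heptamer, at 0.94. That list passed without siBYSL 1 (camera adjusted p = 0.043) and with guide-site genes left out (0.034), but not with an estimated correlation (0.661). Of 71 nuclear genes of the respiratory chain 9 fell and 7 rose (7 and 6 adjusted over the list alone; camera adjusted p = 0.368), among them ATP5F1B (-0.46), NDUFB10 (-0.81), NDUFB3 (-0.64) and ATP5MF (-0.87), the last with a guide-seed heptamer. Without siBYSL 3 their camera adjusted p was 9.8e-05, while with all libraries and an estimated correlation it was 0.884. Of 15 transcripts of the mitochondrial genome 5 fell and 0 rose (2 fell adjusted over the list alone), led by MT-ND4L (-0.43) and MT-ND5 (-0.27). Their camera adjusted p was 0.0609, or 0.661 with an estimated correlation. It was 0.00221 without siBYSL 3, 0.0491 without siNC 3 and 0.036 with guide-site genes left out.

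Genes of the integrated stress response, driven by the transcription factor ATF4, were lower: of 42, 24 fell and 3 rose (26 and 4 adjusted over the list alone; median -0.28). Asparagine synthetase, ASNS, fell from 48.2 to 21.6 CPM (-1.16, SE 0.068), the glutathione-degrading CHAC1 from 22.8 to 10.2 CPM (-1.16), the glycyl-tRNA synthetase GARS1 by 0.74 and the serine-synthesis gene PSAT1, which carried a guide-seed heptamer, by 0.88. Camera gave adjusted p = 3.4e-06, and adjusted p = 0.0978 with an estimated correlation. Of 20 heat shock genes 8 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.00782, and adjusted p = 0.343 with an estimated correlation), with the co-chaperones DNAJB1 at -0.66, FKBP4 at -0.48 and STIP1 at -0.46 and the chaperone HSP90AB1 at -0.32. DNAJB1 carried 2 guide-seed heptamers. Of 30 endoplasmic reticulum chaperone and unfolded protein genes 7 fell and 3 rose (the same adjusted over the list alone; camera adjusted p = 0.211), with XBP1 at -0.46. Of 27 ferroptosis and glutathione genes 9 fell and 4 rose (the same adjusted over the list alone; camera adjusted p = 0.368), with SAT1 at 0.58 and SRXN1, which carried a guide-seed heptamer, at -0.42.

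Among signalling lists the calls of NF-kB, YAP/TAZ and MAPK feedback genes were mostly falls. Of 30 NF-kB and cytokine genes 16 fell and 5 rose (18 and 5 adjusted over the list alone; median -0.28; camera adjusted p = 5.4e-04, and adjusted p = 0.226 with an estimated correlation). Besides IL11 and IL24, BIRC3, an inhibitor-of-apoptosis gene with a guide-seed heptamer, fell from 220.7 to 103.8 CPM (-1.09), and TRAF1 fell by 0.94. Of 23 targets of YAP/TAZ 12 fell and 4 rose (13 and 5 adjusted over the list alone; camera adjusted p = 0.0115, and adjusted p = 0.661 with an estimated correlation). The matricellular genes CCN1 and CCN2 fell by 0.83 and 0.80, ANKRD1 from 1245 to 739.1 CPM (-0.75) and AMOTL2 by 0.88, and 0 of the 12 fallen targets held a guide-seed heptamer. Of 22 MAPK feedback genes 9 fell and 2 rose (10 and 2 adjusted over the list alone), with FOSL1 at -0.80, DUSP5 at -0.57, DUSP1 at -0.58 and EPHA2 at -0.46. Their camera adjusted p was 0.0115, or adjusted p = 0.493 with an estimated correlation and 0.0528 without siBYSL 3. Of 22 immediate early genes 7 fell and 2 rose (the same adjusted over the list alone, camera adjusted p = 0.0518), with ZFP36 at -0.72. This list passed without siNC 1 (0.04), without siNC 2 (0.05) and without siBYSL 2 (0.0478), but not with an estimated correlation (0.343).

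Matrix and adhesion genes went both ways. Of 42 genes of the epithelial-mesenchymal transition and matrix 17 rose and 9 fell (18 and 10 adjusted over the list alone; camera adjusted p = 0.627). The members with the smallest p had fallen, although more members rose; they included the plasminogen activator PLAU, down from 299.9 to 150.9 CPM (-0.99), and its receptor PLAUR (-0.85). Of 18 matrix proteases and inhibitors 6 fell and 5 rose (7 and 5 adjusted over the list alone; adjusted p = 0.627): CTSB rose by 0.62 and TIMP3 by 0.51, while the sheddase ADAM17, which carried a guide-seed heptamer, fell by 0.73 and CTSS by 0.66. Of 19 epithelial genes 7 rose and 6 fell (7 and 7 adjusted over the list alone; adjusted p = 0.627); E-cadherin, CDH1, rose from 4.48 to 9.18 CPM (1.04), EPCAM by 0.54 and ST14 by 0.77, and CLDN4 fell by 0.47. Of 20 TGF-beta response genes 8 rose and 4 fell (9 and 4 adjusted over the list alone; adjusted p = 0.138), with RHOB at 0.86, LTBP2, which rose and carried a guide-seed heptamer, at 0.93 and CCN2 again lower. Of 16 Wnt targets 3 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.627). The Wnt antagonist DKK1 fell from 567.4 to 280.8 CPM (-1.02). At far lower levels, LGR5 rose from 2.4 to 5.3 CPM (1.13) and AXIN2 from 2.8 to 4.7 CPM (0.75). Of 36 receptor kinase and PI3K-AKT-mTOR genes 9 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.781), with INSR at 0.65, IGF1R at 0.70, RHEB at -0.35 and EIF4EBP1 at -0.69; INSR, which rose, carried a guide-seed heptamer.

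Genes of p53 and cell death went both ways, and camera called none of these lists in the main setting. Fry called p53 targets (adjusted p = 5.2e-04), senescence (2.2e-04) and apoptosis genes (0.033) lower. It called autophagy and lysosome genes higher (2.2e-04), but not the interferon, lipid or small RNA lists. Of 29 p53 targets 11 fell and 5 rose (the same adjusted over the list alone; camera adjusted p = 0.0904): CDKN1A, CCNG1 (-0.49) and TNFRSF10B (-0.46) fell, and the stress cytokine GDF15 rose from 15.7 to 32.3 CPM (1.04). CDKN1A and TNFRSF10B carried a guide-seed heptamer, as did 3 of the 11 fallen targets. Of 17 senescence and cell-cycle inhibitor genes 9 fell and 4 rose (the same adjusted over the list alone; adjusted p = 0.107), with IGFBP4 at 0.74. Of 32 apoptosis regulators 10 fell and 6 rose (10 and 7 adjusted over the list alone; adjusted p = 0.376), with BAK1 at -0.53 and MCL1, which carried a guide-seed heptamer, at -0.52. Of 40 autophagy and lysosome genes 13 rose and 9 fell (14 and 9 adjusted over the list alone), with CTSB at 0.62 and ULK2 at 0.72 against TFE3 at -0.53. Their camera adjusted p was 0.0809, 0.0359 with library totals and 0.343 with an estimated correlation. Of 41 interferon response genes 13 fell and 4 rose (the same adjusted over the list alone; adjusted p = 0.138), with HERC5 at 0.46, IFIH1 at 0.44 and IRF1 at -0.32. Among lipid genes, 8 of 25 of cholesterol synthesis fell and 5 rose (9 and 5 adjusted over the list alone; adjusted p = 0.293; INSIG1 0.59), and 5 of 19 of fatty acid synthesis fell and 3 rose (5 and 6 adjusted over the list alone; adjusted p = 0.627; ME1 0.85, MLXIPL 0.93). Of 13 genes of the small RNA machinery 6 fell and 4 rose (6 and 5 adjusted over the list alone; adjusted p = 0.44), with DICER1 at -0.58, AGO2 at -0.47, AGO3 at -0.39 and TNRC6C, which rose, at 0.59; DICER1 and AGO3 carried guide-seed heptamers.

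Most markers of leukocytes, endothelium and mural cells did not pass the count filter or were not in the table. Of 22 leukocyte markers 6 could be tested, of which 3 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.287), and LAPTM5 alone exceeded 12.9 CPM, falling from 166.2 to 83.1 CPM. Of 15 fibroblast and mural cell markers 7 were tested, and 4 rose with 0 falls (the same adjusted over the list alone; adjusted p = 0.0518), ACTA2 from 2.35 to 3.95 CPM (0.74) and PDGFRB from 4.61 to 6.08 CPM (0.40). That list passed without siNC 2 (0.0369) and without siBYSL 2 (0.0451), but not with an estimated correlation (0.343). Of 4 endothelial markers tested, ESAM fell from 134.0 to 92.0 CPM (-0.54) and 0 rose (1 rose adjusted over the list alone); 4 members were too few for a list test. Of 16 luminal epithelial markers 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.198), with ELF3 at 0.68.

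Gene classes differed in the share of genes called by Fisher's exact test (two-sided, Benjamini-Hochberg over 18 tests). Of 2351 lncRNA genes 343 rose (14.6%) and 168 fell (7.15%), against 19.1% and 20.3% of all other genes (adjusted p = 3.2e-07 and 1.2e-61). Of 13361 protein-coding genes 2628 rose and 2796 fell (19.7% and 20.9%). Processed pseudogenes, whose reads can come from their parent genes, were called less often in both directions: of 186, 19 fell (10.2%, against 18.5% of other genes) and 1 rose (0.538%, against 18.7%), with adjusted p = 0.0078 and 7.6e-15. Fisher's test treats genes as independent, although all calls came from the same libraries, so its p-values can overstate the evidence. Low counts can limit calls in the lncRNA and pseudogene classes.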

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

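BYSL stayed between -2.66 and -2.53 on the log2 scale, and the 24 genes with the largest changes under the naming rule kept direction and call in each of 16 settings (384 of 384 values). No called gene was called in the opposite direction in another setting. The count of changed genes was 6093 with DESeq2 size factors, 6637 without a filter, 5843 under the stricter filter, 5467 with the DESeq2 Wald test and 6060 with limma-voom. With library totals 1989 genes were lower against 3027, since that scaling moved the median log2 fold change by 0.078. Genes higher by 1 or more numbered 209 under the stricter filter against 360, as fewer genes were tested. With 1 library left out, changed genes ranged from 4226 to 8004, higher genes from 2121 to 3929, lower genes from 2105 to 4075, genes higher by 1 or more from 340 to 419, genes lower by 1 or more from 158 to 196, BYSL from -2.66 to -2.58 and lists called from 13 to 17. The highest count, 8004, came without siBYSL 3. Of the 15 lists called by camera, 0 kept an adjusted p under 0.05 with an estimated correlation, and 0 other lists gained it. Fry called 24 lists, 11 of the 15 among them. The 13 others included p53, senescence, apoptosis, ferroptosis, RNA polymerase I, endoplasmic reticulum, immediate early, hypoxia and leukocyte lists, all lower. The rest were autophagy, histone, epithelial and fibroblast lists, all higher. For 60S factors and glycolysis the estimated correlations were 0.0033 and 0.0085, below the preset 0.01. Stronger correlation between genes thus does not account for the loss of those calls. For p53 targets the estimate was -0.015, and camera adjusted p still went from 0.0904 to 0.343. A call lost under this setting therefore need not reflect correlation between members. The cause was otherwise not tested. Fry did not call small-subunit ribosomal proteins (adjusted p = 0.468), large-subunit ribosomal proteins (0.407), mitochondrial ribosomal proteins (0.205) or G2/M genes (0.0722). Removing the trend with transcript length gave 7053 changed genes and kept all 15 lists, as did leaving out guide-site genes. The seed difference was -0.15 over all annotated 3′ UTRs and -0.16 for genes of 10 CPM or more. With a replicate block 5566 genes changed (5415 called in both fits, 0 in opposite directions), all 15 lists were kept, BYSL kept its call and the seed difference was -0.16. Deviations of same-numbered libraries correlated at -0.13, 0.060 and 0.011 over genes, and siNC 1 correlated best with siBYSL 3 (0.15), so not every library correlated best with its own number and the numbers were not taken as pairs. Of lncRNA genes 343 rose and 168 fell, against 220 and 111 without siNC 3 and 110 falls without siBYSL 2, settings in which fewer genes of all kinds were called. Depth limits calls for low-count genes, and no test with fewer reads was run.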

Other observations

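The tests of the control siRNA's seeds and of its hexamer in zinc-finger genes were chosen only after the result was seen, as was the choice of the zinc-finger family; predictions for the other tests were written before their values. Zinc-finger genes with ZNF symbols, most of which encode DNA-binding repressors, rose as a family. Of 498 tested 204 rose (41.0%, against 17.8% of other genes) and 19 fell, with a median log2 fold change of 0.26 (Fisher's exact test, two-sided, Benjamini-Hochberg over 360 tests of 180 symbol families, adjusted p = 6.7e-30). That test treats genes as independent, which members of a family need not be, so its p-value can overstate the evidence. ZNF845 rose by 1.28, ZNF629 by 1.20, ZNF704 by 1.16, ZNF721 by 1.12 and ZNF138 by 1.02, and ZNF664 rose from 44.3 to 87.1 CPM (0.98). On chromosome 19, home of many zinc-finger clusters, 104 of 217 coding members rose, and elsewhere 88 of 230. With 1 library left out 152 to 239 rose and 12 to 28 fell. The median was 0.34 with library totals and 0.30 with upper-quartile factors.

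Genes with the heptamer TCGGAGA in the 3′ UTR had the highest z-score (8.80) of the difference in fold change among 15978 heptamers scanned. Of 291 such genes 44.7% rose, against 19.3% of genes without it, and their length-adjusted fold changes lay 0.21 higher (SE 0.029). TPM4, a tropomyosin of actin filaments, rose from 406.3 to 893.3 CPM (1.14), the dynein adaptor BICD2 by 1.04, the sulfotransferase CHST14 by 0.98, DCBLD2 by 0.96, HABP4 by 0.96 and the galactosyltransferase B4GALT1 by 0.95.

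A first pattern was the fall of 3027 genes, weighed against seed pairing by the guide strand of the BYSL siRNA. Genes with a site lay lower by -0.16, the lowest of 630 heptamers, which fits an effect of that seed. Direct pairing through that heptamer in the 3′ UTR does not account for all falls: 19.1% of fallen genes with a 3′ UTR carried it, where more than 50% had been predicted. Other pairing with the guide was not counted. CTGAATA, shifted by 1 base along the target, ranked 2 from the lowest of 15978 heptamers by z-score (1925 genes, difference -0.079, z-score -8.07), although genes with GCTGAATA hold both. Sites in coding sequence and falls downstream of site genes were not counted either. The share therefore cannot exclude the seed as the whole cause. Only 1 siRNA was used per group, so loss of BYSL cannot be told from other effects of the siRNA. Of the 10 splits of the libraries into 3 and 3, the real one gave 6059 changed genes and the highest other 0 (unadjusted, 7667 against 80 to 1092), but 10 splits are too few for a share under 0.05.

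A second pattern was the rise of genes with TCGGAGA. The hypothesis was that siNC libraries hold a control siRNA whose seeds lower such genes, which would then appear higher in siBYSL. The control's sequence is not in the labels, so the seeds of a widely used scrambled control, recalled from general knowledge, were taken: they pair with TCGGAGA and TGTCACG. The rank of TCGGAGA defines the pattern and tests nothing; TGTCACG ranked 10 by z-score from the highest of 15978 heptamers (407 genes, difference 0.11, SE 0.020), which fits the hypothesis, but that rank too was known when the prediction was written, and it does not show which control was used. Either site occurred in 10.0% of risen, 2.97% of fallen and 4.31% of uncalled genes, in NPR3, PALM, NOLC1, LTBP2, TIMP3, ELF3, CA12 and IGF1R among risen genes of the report, but also in SLC7A5 and AGO3, which fell; 73.6% of risen, 69.4% of fallen and 78.2% of uncalled genes held no seed site of either siRNA.

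The third pattern was the rise of ZNF genes. A trend with length, GC content or expression does not account for it: the 447 coding members had a median of 0.24, and 1000 matched sets reached at most 0.098. Exact hexamers of that control's passenger seed (CGGAGA) do not account for it either, since the 257 members without one in coding sequence or 3′ UTR had a median of 0.23, and matched sets reached at most 0.12. The difference in median between the 386 members with the hexamer TGGAGA in coding sequence and the 61 without it was 0.24. It was 0.013 for CGGAGA, 0.061 for AGGAGA and 0.078 for GGGAGA, but in other genes TGGAGA gave 0.055 and CGGAGA 0.084. With 0 and 1 CGGAGA sites in coding sequence the ZNF medians were 0.23 and 0.21. With 2 or 3 sites the median was 0.31 (49 members), and with 4 to 7 it was 0.74 (4 members). Whether the 61 members differ from the 386 in type of zinc finger was not tested. Pairing with a wobble base and sites of that control's guide seed were not tested. Reads shared between similar ZNF genes were not tested either, and a biological cause could not be separated from the siRNAs.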
